A study of Arabidopsis thaliana with 12 samples.

How the data were processed

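The series compared the toc90 mutant of Arabidopsis thaliana with WT, with 6 readings in each group. Groups and numbers 1 to 6 were taken from the sample titles. The deposited values were array intensity values, 1 channel per sample per the labels. They ran from 0 to 100, and 5 columns reached 100 within a tolerance of 1e-06. The scanner, background step, scaling, averaging of spots and gene build used by the authors to make this intensity are not given in the sources used here, so the scale of the values is unknown beyond its floor at 0. Zeros were read as values at the floor. No column without a sample was used. The numbers of arrays and the floor limit the precision of dim probes.

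Genes were named through the platform annotation of the array, updated through a reference gene table of the assembly TAIR10.1, of which no coordinates were used. Of 3439 probes, 692 had 1 gene, 870 had several and 1877 were not listed and are unnamed here. Of the 692, 690 matched the reference table. No gene was named from a probe with several.

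Values were put on the log2 scale with zeros as missing. Column medians differed by more than the limit set before the data were examined, so columns were quantile normalized. A probe needed at least 3 values in each group, which left 2687 tested and 752 not tested. Differences were tested, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, at a Benjamini-Hochberg adjusted p under 0.05. Gene lists of at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, fry and exact permutation as alternatives. The design, the 17 gene lists, the rule for named genes and the first alternatives were chosen before the data were examined. Lists added later were drawn up after the annotation and the overall counts had been seen, but before results of single genes had been seen.

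Named genes were those of the import machinery that passed or belonged to its core, the 8 probes with the largest rise and the 8 with the largest fall past the threshold, and up to 3 passing members of each fixed list. The rule was applied to single-gene probes, which gave 18 genes. Other genes named in the text are further list members, or were chosen after their values were seen, as stated there.

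Column measures were compared with exact permutation tests over the 924 assignments of the 12 readings. The alternatives were median scaling, cyclic loess, values as deposited, zeros at the lowest positive value, an offset of 0.0274 before log2, leaving out the 25% of probes with the lowest means, the number as a replicate block, pairs of readings averaged, array weights, trend and robust variance and each reading left out. Alternatives chosen after seeing the data were a random block of neighbouring numbers, averages with the number pair as a replicate block, an equal share of zeros, probes with values in all 12 columns, centred columns, pairs of numbers left out, and quantile normalization within each class of ID block, with and without averaging. Probe IDs were grouped in blocks of 96, the size being chosen after several sizes and periods had been looked at.

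The limma fit was tested on 20 simulated data sets of 2687 probes, 200 of them changed, for toc90 against WT. With independent readings, 40.5% of changes of 1 in log2 and 76.1% of changes of 2 were recovered, and 16.4% of calls were false. With a correlation of 0.518 between neighbouring readings, 39.5% of the calls from 12 readings were false. With neighbouring readings averaged, 9.6% and 46.9% were recovered, and 16.8% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.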

Results

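Total RNA of Arabidopsis thaliana was measured on an array with 1 channel per sample. The samples were 6 readings of the wild type (WT, ecotype Columbia 0) and 6 readings of the toc90 mutant in the same ecotype, which per the labels has impaired import of proteins into chloroplasts. Each group was numbered 1 to 6. The tissue and growth conditions are not given in the sources used here, and the labels do not state whether readings came from separate plants or cultures. The p-values therefore measure the spread between these samples, which may be technical. The table held 3439 probes, of which 692 had 1 annotated gene, 870 had several and 1877 were unnamed here. The number of arrays limits the precision.

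The 2 groups differed in their dim probes before any comparison of single genes. The share of probes listed at 0 was 15.2% ± 1.63 in WT and 26.6% ± 5.37 in toc90 (SD, n = 6 each, two-sided exact permutation p = 0.00216). The median value was 0.154 ± 0.00264 in WT and 0.0619 ± 0.00363 in toc90 (SD, n = 6 each, two-sided exact permutation p = 0.00216). The mean value was 0.865 ± 0.126 in WT and 0.85 ± 0.162 in toc90 (SD, n = 6 each, two-sided exact permutation p = 0.671). With readings of neighbouring numbers averaged, 3 values against 3, the exact permutation p of the share of zeros and of the median was 0.1 each, the smallest that this design allows.

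**Figure D1:**
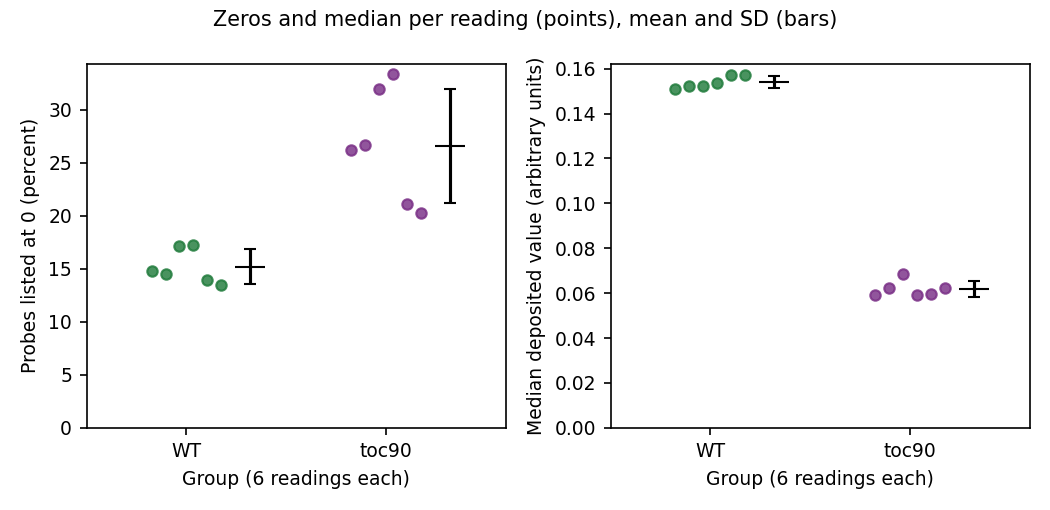
Share of probes listed at 0 (left, percent) and median deposited value (right, arbitrary units) in each of the 12 readings, with the mean and SD of each group as bars. The toc90 readings had a mean of 26.6% zeros against 15.2% in WT, and a mean of the medians of 0.0619 against 0.154.

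The comparison of toc90 with WT asked which transcripts differ in a mutant with impaired chloroplast protein import. Of the 8 single-gene probes with the largest falls, the 3 with the highest values in WT were AT1G76450, AT3G04650 and AT1G13370. AT1G76450, which encodes a PsbP-domain protein of the thylakoid lumen, fell from 2.67 ± 0.421 to 0.0839 ± 0.0548 (deposited values, SD, n = 6 each), a log2 difference of -4.53 ± 0.26 (SE, limma adjusted p = 2.05e-06). AT3G04650 fell from 1.34 ± 0.168 to 0.0908 ± 0.0485, a log2 difference of -3.35 ± 0.17 (SE, limma adjusted p = 7.25e-07). AT1G13370, which encodes a histone H3-like protein, fell from 0.788 ± 0.12 to 0.0519 ± 0.0276, a log2 difference of -3.62 ± 0.32 (SE, limma adjusted p = 2.05e-05). For these 3 genes all 6 toc90 readings lay below every WT reading. Each was also called with neighbouring readings averaged (limma adjusted p = 0.00647 for each).

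The other 5 of the 8 largest falls on single-gene probes were AT1G73430 (-8.39), AT1G62780 (-4.10), AT5G56070 (-3.54), AILP1 (-3.48) and AT3G09250 (-3.48), in log2. AILP1 and AT3G09250 stayed below an adjusted p of 0.05 in limma with neighbouring readings averaged, at 0.0436 and 0.0181. Numbers 3 and 4 of toc90 were both at 0 for AILP1, so its test had no average for them. AT5G56070, AT1G62780 and AT1G73430 did not, at 0.0586, 0.163 and 0.103. The log2 difference of AT1G73430 had an SE of 1.81, and 2 of its 6 toc90 readings were listed at 0. Its other toc90 readings ran from 4.73e-05 to 0.0462 and those of AT1G62780 from 0 to 0.0487, and with an offset the differences were -3.48 and -1.71. With zeros set to the lowest positive value AT3G04650 stood at -5.07 (limma adjusted p = 0.118) and AT1G62780 at -3.88 (0.0821), each with 1 toc90 reading at 0 that the values above leave out. AT1G76450, also with 1 such reading, stood at -5.87 (0.0373) in that setting. AILP1 and AT3G09250, with 2 such readings each, stood at -6.55 (0.0306) and -6.34 (0.0405).

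The 8 largest rises on single-gene probes had log2 differences of 1.61 to 3.58 and lay near the floor, with deposited group means of at most 0.075. In log2 they were AT2G47390 (3.58), AT3G09850 (2.96), AT2G27630 (2.85), CSLA01 (2.3), AT3G49740 (1.72), CBL (1.69), AT1G11800 (1.66) and AT3G08000 (1.61). CSLA01 belongs to the cellulose synthase-like family, and CBL encodes cystathionine beta-lyase of methionine synthesis. Each of the 8 had at least 1 toc90 reading listed at 0, which the log2 fit left out. CBL was 0.0521 ± 0.0145 in WT and 0.0525 ± 0.0858 in toc90 (deposited values, SD, n = 6 each), and its log2 difference turned to -0.45 with zeros set to the lowest positive value. AT1G11800 had a lower deposited mean in toc90, at 0.0319 ± 0.0302 against 0.0363 ± 0.0155 in WT (SD, n = 6 each). Of its 6 toc90 readings 4 lay below the WT mean and 2 above it. With values as deposited it was not called (0.41, limma adjusted p = 0.494). AT2G27630 had 5 of 6 toc90 readings above every WT reading (limma adjusted p = 0.00108, and 0.0207 with neighbouring readings averaged). The averaged test had no WT average for numbers 5 and 6, both at 0 for AT2G27630. Its WT mean was 0.00609 with 3 of 6 readings at 0, so the size of its rise is not fixed, at 1.43 with an offset and 7.3 with zeros at the lowest positive value. AT2G47390 and CSLA01 were also called with neighbouring readings averaged, at limma adjusted p of 0.0181 and 0.0251, but with their zeros left out. With zeros at the lowest positive value the adjusted p was 0.565 and 0.309, and 3 and 2 of their 6 toc90 readings lay below every WT reading. The remaining 5 were not called with neighbouring readings averaged.

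**Figure D2:**
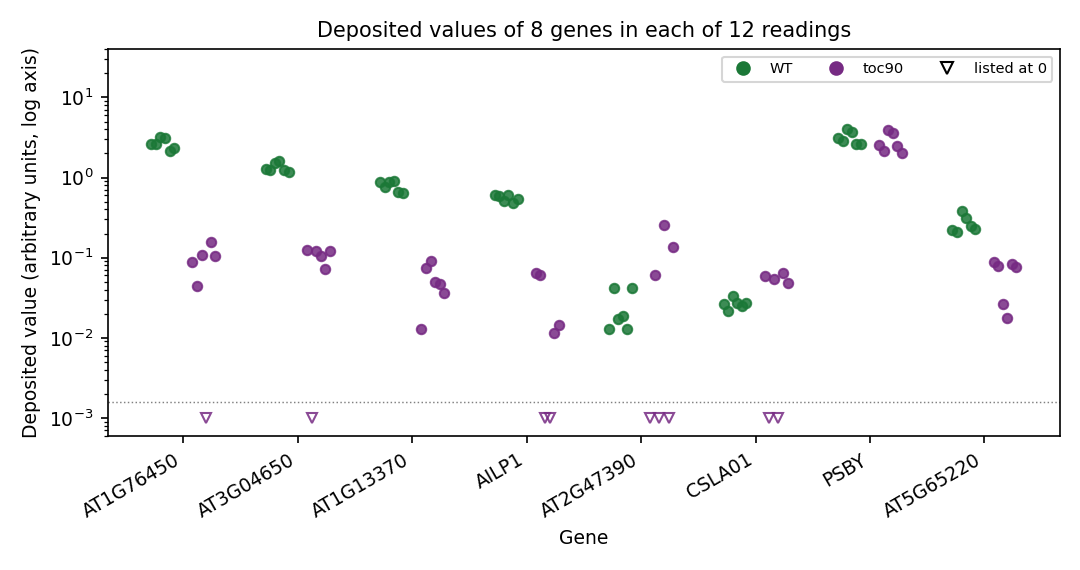
Deposited values (arbitrary units, log axis) of 8 genes in each of the 6 WT and 6 toc90 readings; open triangles below the dotted line mark readings listed at 0. All toc90 readings of AT1G76450, AT3G04650, AT1G13370 and AILP1 lie below the WT readings, with 1, 1, 0 and 2 of them at 0. Of the toc90 readings of AT2G47390 3 are at 0, and of those of CSLA01 2. PSBY overlaps between groups, and its fitted difference of -0.44 turned to 0.50 with median scaling.

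Over all probes, limma called 643 of 2687 at a Benjamini-Hochberg adjusted p under 0.05, with 186 higher and 457 lower in toc90. The median of all tested probes was -0.21 in log2, and relative to it AT1G76450 stood at -4.32, AT3G04650 at -3.14 and PSBY at -0.23. Single-gene probes gave 28 higher and 101 lower calls of 538 tested. Over all probes, the number as a replicate block left 418 calls (118 higher and 300 lower). Averaging numbers 1 and 4, 2 and 5, and 3 and 6 left 472 calls. Averaging neighbouring readings left 107 calls (30 higher and 77 lower), 104 of them the same probes and direction as among the 643. Fitting those averages with the number pair as a replicate block, chosen after seeing the data, left limma 0 calls, with 588 probes at an unadjusted p under 0.05. In the simulated data sets, 16.4% of calls from 12 readings were false with independent readings and 39.5% with correlated neighbours. With correlated neighbours averaged it was 16.8%. In neither fit did the adjusted p under 0.05 hold false calls to that share. Of the 643 calls, 28.9% were higher in toc90. That share was 56% with median scaling (431 higher, 339 lower), 51% with cyclic loess (180 and 173), 8.66% with values as deposited (85 and 896), 52.6% with zeros at the lowest positive value (180 and 162) and 46% with an offset (284 and 334). With the added settings it was 57.1% with an equal share of zeros (286 and 215) and 48.9% with each column centred (288 and 301).

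Calls among photosynthesis transcripts depended on the scaling. Of 6 tested members of the joined lists, 0 were higher and 1 lower over all probes tested. Median scaling gave 4 higher and 0 lower, cyclic loess 1 higher and 0 lower. With values as deposited, zeros at the lowest positive value, an offset, an equal share of zeros or centred columns, 0 were higher and 0 lower. Of the photosystem II genes, 1 of 4 tested members fell over all probes tested, and 2 of 4 adjusted over the list alone. The called member was PSBY, a small photosystem II protein, at 3.16 ± 0.579 in WT and 2.80 ± 0.775 in toc90 (SD, n = 6 each, log2 difference -0.44 ± 0.13, SE, limma adjusted p = 0.0285). PSBY turned to 0.50 (limma adjusted p = 0.0295) with median scaling, and had an adjusted p of 0.298 with neighbouring readings averaged. The antenna gene LHB1B2 (-0.36, limma adjusted p = 0.083, adjusted over the list alone 0.0494) and PSBW (-0.35, 0.171) did not pass over all probes, and both turned above 0 and were called with median scaling, at 0.66 (limma adjusted p = 0.00839) and 0.54 (0.0223). PSAN of photosystem I did not pass (0.18, limma adjusted p = 0.463), but was called higher with median scaling (1.2, 0.00018) and cyclic loess (0.46, 0.0308), with 5 of 6 toc90 readings above every WT reading. PSB27 (0.03, 0.941) and PRK of the Calvin cycle (-0.43, 0.153, and 0.50 with median scaling) did not pass in these settings.

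Of the plastid ribosomal protein genes, 1 of 5 tested members fell over all probes, and 1 of 5 adjusted over the list alone. It was AT5G65220, which encodes protein L29 of the plastid ribosome, at 0.269 ± 0.0686 in WT and 0.062 ± 0.0313 in toc90 (SD, n = 6 each, log2 difference -1.60 ± 0.46, SE, limma adjusted p = 0.0266). All 6 toc90 readings lay below every WT reading, and the adjusted p was 0.199 with neighbouring readings averaged. As a group the 5 genes gave no call against the other probes (limma camera p = 0.941, and p = 0.515 with an estimated correlation). Fry, which does not compare a list with other genes, gave a Benjamini-Hochberg adjusted p of 0.0271. The tetrapyrrole genes CHLM (-0.17, limma adjusted p = 0.616) and AT1G74470 (-0.46, 0.0934) did not pass, and AT1G74470 turned to 0.53 (0.0465) with median scaling. NTRC did not pass (0.29, limma adjusted p = 0.324), but was called with median scaling (0.82, 0.0173), an offset (0.55, 0.0372) and an equal share of zeros (0.64, 0.0344). The fatty acid genes FATB (0.16, limma adjusted p = 0.677) and AT1G24360 (-0.35, 0.388) did not pass, but with values as deposited both were called lower (-0.68, 0.0448, and -1.11, 0.017).

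Of 17 gene lists fixed before the data were examined, 10 had no tested member on a single-gene probe, and 1 had enough members for a list test. None of the 31 genes of the import machinery was on a single-gene probe, and no annotated probe was listed for TOC90, so its level was not analysed here and the labels were not checked by it. Among the lists added after the annotation was read, none of the 6 with enough members passed limma camera with Benjamini-Hochberg adjustment over 7 lists (lowest adjusted p = 0.375). These covered the joined photosynthesis genes (0.865), thylakoid assembly factors (0.375), metabolic enzymes (0.983), chaperones and redox proteins (0.375), pentatricopeptide repeat proteins (0.928) and flower and meristem regulators (0.928). The joined photosynthesis genes turned from -0.14 to 0.60 relative to the median of all probes, and were called, with median scaling (camera adjusted p = 0.00966). Their WT means ran from 1 (PSB27) to 49.1 (PSBW), against a median WT value of 0.154. The median log2 ratio of toc90 to WT was 0 for probes above 3.2 in WT. It was -0.24 between 0.8 and 1.6, and -0.92 between 0.2 and 0.4. Median scaling leaves this difference by level, so the rise of these bright genes cannot be told apart from it. With an estimated correlation, on members without zeros only, the camera adjusted p was 0.901, 0.715, 0.951, 0.682, 0.951 and 0.951.

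The log2 differences also varied with the place of a probe in the numbering of the array, a pattern noticed after seeing the data. Probes were grouped in 48 blocks of 96 consecutive IDs, and each block was given its place in runs of 3. The mean level-adjusted difference was 0.2 in the first place, -0.49 in the second and -0.16 in the third. The range of these means was largest for numbers 5 and 6 of toc90, at 1 against 0.5 for numbers 1 and 2 and 0.55 for 3 and 4, with the first place at 0.34, 0 and 0.07. Over all readings the range of 0.69 had a permutation p of 1e-04, the smallest that the shuffles can give, with the block size and the run of 3 picked on the same data. Lower calls made up 10.2% of 940 tested probes in the first place, 23.2% of 839 in the second and 18.3% of 908 in the third. Called falls of more than 2 in log2 numbered 5, 73 and 42, and lower calls with neighbouring readings averaged 5, 48 and 24. Of the 8 largest falls named above, 0 lay in the first place, 4 in the second and 4 in the third. Quantile normalization within each place gave 617 calls (183 higher and 434 lower), and 92 (25 and 67) with neighbouring readings averaged, and calls moved between places. Lower calls went from 96 to 168 in the first place and from 195 to 125 in the second, and higher calls from 81 to 35 and from 45 to 68. The falls of AT1G76450, AT3G04650 and AT1G13370 remained called in that last setting, at limma adjusted p of 0.0101, 0.011 and 0.0101.

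**Figure D3:**
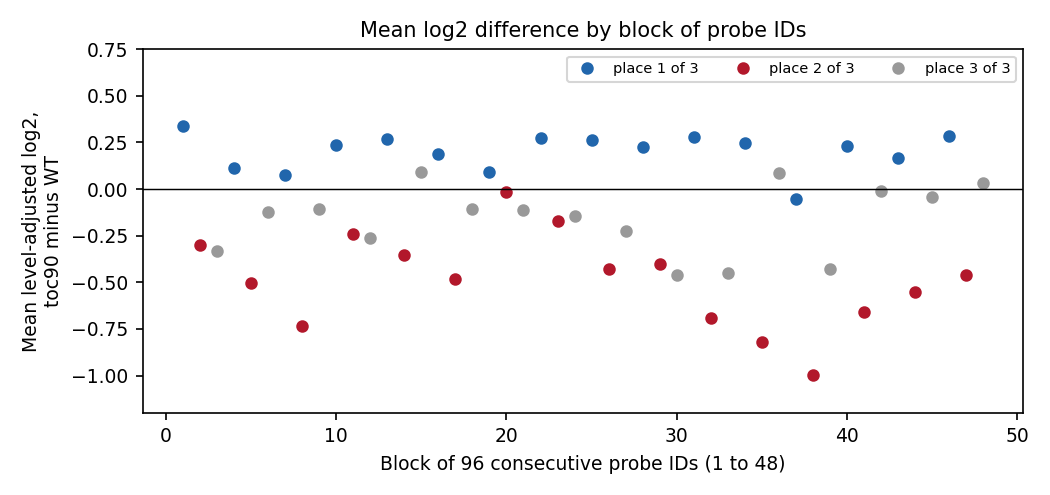
Mean level-adjusted log2 difference, toc90 minus WT, in each of 48 blocks of 96 consecutive probe IDs, coloured by the block's place in runs of 3. Of the 16 blocks in the first place 15 lie above 0, and of the 16 in the second place 0 do.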

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

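The tests of dim probes, ID blocks and neighbouring readings were chosen after the result was seen. The test of a constant replaced one on probes above 3.2 in WT (median log2 ratio 0, 95% bootstrap interval -0.07 to 0.1), which had left it undecided. The splits of the readings were planned. Of 41 sets of 6 readings, 1 had a reading far from the others, and chance gives about 1 in 20. It was the median value of reading 3 of toc90, at 0.0687, against 0.0623 for the nearest and 0.0592 for the farthest of the group.

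Dim probes had lower values in toc90, with a median log2 ratio of -0.92 for probes between 0.2 and 0.4 in WT and 0 above 3.2. A smaller scale factor would have lowered both alike, so -0.92 argues against it. A single larger constant taken off every probe would have lowered probes of like level equally, but class 2 of the ID blocks lost more than class 1 in deposited units (difference -0.0933, 95% bootstrap interval -0.113 to -0.08). Lower levels of all weakly expressed genes alike in the mutant would also have left no class difference, which was -0.95 in log2 (-1.1 to -0.74) in the third quartile of WT level. A constant that varies over the array may account for part of the drop and was not tested, and neither was an effect of the genotype on single genes.

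The difference also varied with the place of the 96-ID block. Position or printing on the array and a different gene content of the classes cannot be told apart, because either would give the permutation p of 1e-04, the smallest possible. The block size and the run of 3 were also picked on the same data. The classes did differ in brightness, with 9.35%, 20.2% and 15.8% zeros in WT for classes 1, 2 and 3. Brightness as the only source of the pattern is argued against by -0.95 between classes 2 and 1 at like WT level. That value was -0.76, -0.74 and -1.04 for numbers 1 and 2, 3 and 4, and 5 and 6 of toc90. Gene content was not tested, so an effect of the genotype stays open.

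Readings with neighbouring numbers deviated together in WT, with correlations across probes of 0.43 to 0.52. In toc90 the correlations were 0.13, -0.08 and 0.35, where unrelated readings taken from a mean of 6 would give about -0.2. Other number pairs reached at most -0.18 in WT and -0.14 in toc90, a smallest gap of 0.06. Pairs of readings may be 2 readings of 1 hybridisation or extract, which this gap of 0.06 is in line with, though it is small and rests on numbers 3 and 4 of toc90 at -0.08. Genes are not independent replicates, and no biological explanation was tested.

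Of 100 splits of the 12 readings into 6 and 6, 1 gave as many calls as the real one, the real split itself with 643, and the highest other gave 2. Chance assignment of independent readings was thereby excluded, but not that of fewer independent samples. With neighbouring numbers averaged, 1 of 10 splits gave as many as the real 107 calls, again the real one, and the highest other gave 0, but 10 splits are too few for a share under 0.05.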

How the results depend on the processing

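Chosen after seeing the data were the random block, the averages with the number pair as a block, the equal share of zeros, centred columns, values in all 12 columns, pairs of numbers left out and quantile within classes of ID block. The cause was not tested unless stated. Against 643 calls (186 higher, 457 lower), cyclic loess gave 353 (173 lower) of 1474 probes tested, values as deposited 981 (85 higher, 896 lower), zeros at the lowest positive value 342 (162 lower), and averaging numbers 1 and 2, 3 and 4, and 5 and 6 gave 107 (30 higher, 77 lower). Median scaling gave 431 higher calls and an offset 284 higher. The number as a replicate block gave 418 (118 and 300). Same-numbered readings correlated at 0.08 to 0.25 across groups (mean 0.16, other pairs -0.03, at most 0.11), 12 of 12 best with their own number. This tie by number was left out of the fits with 643 and 107 calls. A random block of neighbouring numbers gave 277 (68 and 209), and the averages with the number pair as a replicate block gave 0 (0 and 0; 588 at an unadjusted p under 0.05). Higher and lower calls were 286 and 215 with an equal share of zeros and 288 and 301 with centred columns. With values in all 12 columns, 118 were higher. Without numbers 1 and 2 there were 398 (104 and 294), without 5 and 6 327 (67 and 260), and without 3 and 4 284 lower. Quantile within each class of ID block with averaging gave 92 (25 and 67). These counts moved more than 1.5 times, and fewer samples or probes were tested where readings were averaged or left out or loess was used. Leaving out each reading gave 475 to 620 calls, with 141 to 177 higher and 332 to 450 lower. CBL turned to -0.45 with zeros at the lowest positive value, PSBY to 0.50 with median scaling and the joined photosynthesis genes to 0.60 with median scaling (relative to all probes). Fry tests members without zeros against no change. It called plastid ribosomal proteins (3 of 5, adjusted p = 0.0271, list median -0.403, relative to all probes -0.20), joined photosynthesis genes (0.0122) and chaperones (3 of 6, 0.0271). Exact permutation of list means gave adjusted p 0.0303 for thylakoid assembly factors, metabolic enzymes and pentatricopeptide repeat proteins and 0.0417 for chaperones. It took readings as independent and dropped zeros, which can raise toc90 means. Camera with estimated correlation gave 0.715, 0.951, 0.951 and 0.682. The enzymes pointed down in main camera, but their median relative to all probes was 0.0378 and permuted mean 0.18. Of the 18 named genes, 8 kept direction and call with neighbouring readings averaged, 8 with the number as a replicate block, 16 within classes of ID block, 12 as deposited, 13 with median scaling and 7 with zeros at the lowest positive value. Leaving out 1 reading ended the call of AT3G49740 in 9 of 12 cases (highest adjusted p 0.104), AT1G62780 in 7 (0.0724), PSBY in 5 (0.0614), AT1G11800 in 2 (0.0597), AT3G09850 in 2 (0.0589) and AT5G65220 in 1 (0.0542). A turn of sign in a value uncalled in both settings was not counted. Normexp was not run, because the background step is not given here. TOC90 has no value under any setting. The median SD in toc90 was 1.15 log2 for probes between 0.05 and 0.1 in WT and 0.4 above 3.2.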

Other observations

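The genes in this part were chosen after their values were seen, apart from the lists. Of the flower and meristem regulators, 1 of 7 tested genes rose and 2 fell. The MADS-box gene AGL103 rose from 0.187 ± 0.0182 to 0.345 ± 0.0602 (deposited values, SD, n = 6 each, log2 difference 1.35, limma adjusted p = 0.000186, and 0.0471 with neighbouring readings averaged), with 6 of 6 toc90 readings above every WT reading. Its direction and call held under all 8 scalings tried, at 0.87 to 2.11 in log2. The auxin response gene IAA31 fell (-0.96, limma adjusted p = 0.00204), and SPL fell (-1.46, 0.00825), but neither was called with neighbouring readings averaged, at 0.111 and 0.103. IAA31 was not called with median scaling (-0.24, 0.378), nor SPL with zeros at the lowest positive value (-2.82, 0.301). Of the thylakoid assembly factors, 1 of 11 tested genes rose and 1 fell, but calls depended on the scaling. With median scaling PIFI (0.85, limma adjusted p = 0.0104) and AT1G22700 (1.07, 0.00709) were also called higher. NdhS turned from -0.39 to 0.68 (0.00691) in that setting. PIFI and AT1G22700 were each called higher in 5 of 8 scalings. PAC, which is needed for chloroplast development, rose by 0.76 in log2 (limma adjusted p = 0.0244) and stayed called under all 8 scalings, but not with neighbouring readings averaged, at 0.171. CRR21 fell (-1.27, limma adjusted p = 0.00657), but was not called with neighbouring readings averaged (0.0842) or with zeros at the lowest positive value (-2.48, 0.276). Of 15 pentatricopeptide repeat genes 1 rose (AT3G49740) and 3 fell (CRR21, AT2G17670 and AT3G26630), 0 of them called with neighbouring readings averaged, and AT3G26630 turned from -0.56 to 0.59 (limma adjusted p = 0.0192) with median scaling. CBL was the 1 call among 16 metabolic enzymes and CSLA01 the 1 among 3 cell wall genes, and 0 of 6 chaperones and redox proteins were called. As deposited, CBL was not called (limma adjusted p = 0.381), but PPDK (0.0332), AT5G58330 (0.00651), AT-HF (0.0386), AT1G24360 (0.017) and FATB (0.0448) were called lower. With median scaling THIC (0.0132), CYN (0.0192) and AT1G74470 (0.0465) were called higher and AT5G58330 (0.0418) lower. Cpn60beta4 was called higher with zeros at the lowest positive value (0.000268) and an offset (0.001), and NTRC in 3 of 8 scalings.

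Calls passing in turn with 12 readings, with neighbouring readings averaged, within each class of ID block, with median scaling, as deposited, and within class with averaging numbered 73, of which 16 were higher and 57 lower. Of these, 21 lay on single-gene probes, 4 higher and 17 lower. Beside genes named in the report they included AT1G16080 (-3.35 in log2) and AT1G01080 (-3.07), an RNA-binding protein gene. The 4 higher genes were AGL103, CSLA01, AT2G27630 and AT2G47390. These settings leave zeros out. With calls also required in both settings that keep zeros (zeros at the lowest positive value, and an offset), 43 were left (9 higher and 34 lower), 14 of them on single-gene probes (2 higher and 12 lower). AGL103 and AT2G27630 were the 2 higher ones, and CSLA01 and AT2G47390 were not among them. None of the 73 passed in limma when the averages were fitted with the number pair as a replicate block, a setting with 0 calls and 588 probes at an unadjusted p under 0.05.

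Probes above 0 in all WT readings and at 0 in all toc90 readings numbered 21, and 0 showed the opposite. Zeros were more frequent in toc90 over all probes (26.6% against 15.2%), and these probes were not tested apart from that excess. The single-gene ones were AT3G50350, AT3G20150, AT2G47360 and Z-ISO, a carotenoid isomerase gene, which are listed at 0 in toc90 and so carry no fold.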
